A study of Arabis alpina with 16 samples.

How the data were processed

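The study measured RNA from main shoot apices of Arabis alpina Pajares with 16 two-dye Agilent arrays, 1 per slide, in 4 groups of 4 biological replicates: plants after 2 or 8 weeks in long days (16 hours of light, 20 °C by day and 18 °C by night), and plants of both ages after a further 4 weeks at 4 °C in short days (8 hours of light). Each replicate was a pool of apices enriched for the main shoot apex, harvested 8 hours after lights on. Per the labels, the sample was labelled with Cy5 and a pool of the 16 RNAs, the common reference, with Cy3.

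For each array the scanner table holds mean spot signals and median local backgrounds as intensity per the file headers, without normalization. The processed signals, also deposited as intensity, were background subtracted, spatially detrended and dye normalized by Agilent Feature Extraction 9.5.3.1, and the LogRatio column is a log10 ratio of Cy5 to Cy3 per the file headers. Other columns are flags per spot, per the file headers, for spots well above background, saturated or outlying. 15 arrays were read with protocol GE2-v5 and 1, 8wk_LD_4wk_V replicate 3, with GE2-v4. The headers give 2 scan days: 2wk_LD replicate 1 and 8wk_LD replicate 3 were scanned on the first and the other 14 arrays on the second. The deposited matrix holds log2 ratios of sample to reference pool for 29936 Arabidopsis gene models (28721 loci), made by the authors, who name limma and RMA without their role or version. Its values are logs of ratios rounded to 2 decimals, and how the authors joined probes to gene models is not stated. Neither the direction of the ratio nor its centring is stated. The direction was checked against the scanner data: among the 300 most variable gene models, the probe with the closest profile had a positive correlation for 293, with a median absolute r of 0.997.

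Median signals per array were 78.8 to 140 in Cy5 and 52.6 to 67.3 in Cy3, over local backgrounds of 40.5 to 44 and 30 to 38, and 63.1% to 79.6% of the probes in Cy5 and 49.9% to 70.6% in Cy3 stood well above background.

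Probe values came from the scanner tables. Background was removed with normexp (offset 50), log2 ratios of Cy5 to Cy3 were loess normalized within each array with control spots given no weight, and no scaling was made between arrays (limma 3.58.1, R 4.3.3, statmod 1.5.0). Of 241399 probes, 3248 marked as outliers on any array were left out. The 169479 probes that stood well above background in Cy5 on all 4 arrays of at least 1 group were tested, and 68672 dimmer ones were not. No column used here pairs probes with genes. Genes are therefore read from the deposited matrix, from the 27553 gene models whose values vary, while 2383 with the same value on all arrays were not tested.

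Both kinds of value went through the same limma model, with 1 mean per group over all 16 arrays and moderated variances (lmFit, contrasts.fit, eBayes), in 5 contrasts: vernalization at 8 weeks, vernalization at 2 weeks, age before vernalization, age after it, and their interaction. P values were adjusted by Benjamini-Hochberg over all features of a contrast, and an adjusted p under 0.05 is called past the test. Replicate numbers name separate pools in each group and do not pair the samples, so no block was used. Counts of probes were chosen as the main count of each contrast, and 17 gene lists with 293 genes were fixed, before the data were examined; 281 of the genes had a tested gene model. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the 85 tests of 17 lists in 5 contrasts, and again with an estimated correlation. The lists are floral transition and inflorescence identity, floral organ identity, FLC clade and vernalization pathway, SPL family, AP2-like targets of miR172, photoperiod and circadian clock, cold acclimation, flavonoid and anthocyanin synthesis, photosynthesis (green leaf tissue), cell cycle and DNA replication, shoot meristem and leaf primordium, gibberellin metabolism and signalling, salicylate and jasmonate defence, heat shock proteins, glucosinolate synthesis, vascular tissue markers and trichome and stomatal lineage markers, with symbols assigned through Arabidopsis locus numbers.

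Named genes followed a fixed rule: 15 flowering genes in every comparison (FLC, FT, SOC1, LFY, AP1, FUL, TFL1, SVP, VIN3, AP2, SPL3, SPL4, SPL5, SPL9 and SPL15), up to 4 members of each list with the smallest adjusted p, and at most 2 rising and 2 falling gene models outside the lists, since no gene names come with the files. Members were taken in order of adjusted p, but how many of the 4 are printed for each list was chosen after the values were seen. For the 13 listed genes with several varying gene models, the one with the lowest number stands for the gene, because the matrix holds no intensities to choose by. A parenthesis after a value, with an adjusted p and an array, is given where leaving out 1 array ended or made the call. Its adjusted p is the one farthest from the main one. Where over 1 array did so, their number follows: 1 of 4 such arrays means that each of 4 arrays, left out alone, did so. For a list that was not called, the adjusted p values after the first are those that made a call.

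The model was tested on simulated independent noise without group differences. Of changes of 0.5 log2 units added, 64.2% to 79.1% were recovered among probes and 65.7% to 92.5% among gene models over the 5 contrasts. Of changes of 1 unit, 91% to 97% and 89.6% to 98.5% were. A shift of 0.3 in 1 list was called in 3 of 3 contrasts that held it and in 0 of 82 other tests. Alternatives changed the background correction, the normalization, the channel, the filter, the source of values, blocks for replicate number and for scan day, the groups in the fit, the correlation of the list test, the gene model that stands for a gene, and the arrays, each of which was left out in turn. Pairs of arrays left out, scan day 2 alone, median centring of deposited values and gene models by SD were added after seeing the data. Counts of each contrast were also taken over the 35 splits of its 8 arrays, or 100 drawn splits for the interaction. Figures used matplotlib 3.10.9.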

Results

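RNA was measured in main shoot apices of Arabis alpina, accession Pajares, a perennial relative of Arabidopsis. Plants were started at 2 ages, 2 or 8 weeks in long days, and sampled either then (groups 2wk_LD and 8wk_LD) or after a further 4 weeks of vernalization at 4 °C in short days (2wk_LD_4wk_V and 8wk_LD_4wk_V). Each group held 4 arrays, and each array 1 biological replicate, a pool of apices, in Cy5 beside a common Cy3 reference pooled from the 16 RNAs. Per the labels, plants started at 2 weeks are not competent to flower and remain vegetative after the cold, while those started at 8 weeks are competent and are induced by it. Vernalized plants were also 4 weeks older than their controls and in short days, where harvest, 8 hours after lights on, falls at lights off. The median Cy5 signal per array was 78.8 to 140, over a local background of 40.5 to 44, and 63.1% to 79.6% of the probes stood well above background in Cy5. The number of arrays limits the precision of every value.

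On the first principal component of the tested probes, with 48.7% of the variance, the arrays separated by starting age, and on the second, with 18.5%, by vernalization. Between arrays of a group, log ratios correlated across probes at 0.79 to 0.87 in 2wk_LD, 0.74 to 0.89 in 8wk_LD, 0.56 to 0.79 in 8wk_LD_4wk_V and 0.42 to 0.86 in 2wk_LD_4wk_V, and pairs from different groups at -0.48 to 0.63. In 2wk_LD_4wk_V the highest values were 0.862 for replicates 1 and 2 and 0.751 for replicates 3 and 4, and the other 4 pairs lay at 0.417 to 0.488.

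**Figure D1:**
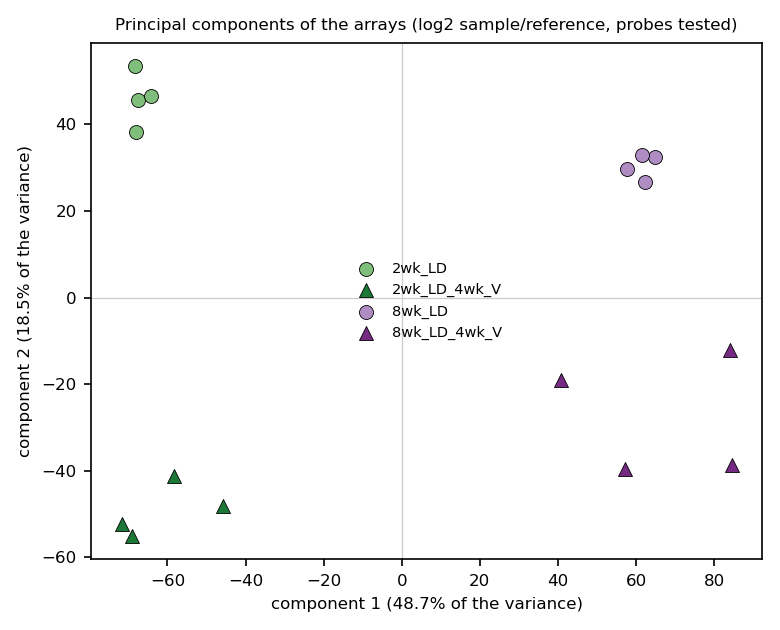
Principal components of the 16 arrays, from normalized log2 ratios of sample to reference pool at the tested probes, with 1 point per array and the share of variance on each axis. The first axis holds 48.7% of the variance and the second 18.5%, and the 4 arrays of 2wk_LD_4wk_V spread more widely than those of 2wk_LD.

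The comparison of 8wk_LD_4wk_V with 8wk_LD asks which genes respond when the cold falls on plants old enough to be induced to flower. Values here and below are log2 fold changes ± the limma standard error, with n = 4 arrays in each group. In parentheses, 1 of 15 such arrays means that each of 15 arrays, left out alone, ended or made the call. FLC (AT5G10140.1), the floral repressor known as PEP1 in this species, fell by 1.40 ± 0.15, and TFL1 (AT5G03840.1), which keeps meristems from taking floral identity, fell by 1.24 ± 0.14. FUL (AT5G60910.2), a MADS-box gene of the inflorescence and fruit, rose by 1.13 ± 0.11, and FD (AT4G35900.1), the bZIP partner of FT, rose by 0.62 ± 0.08. Among the SPL genes, most of which are targets of miR156, SPL5 (AT3G15270.1) rose by 0.96 ± 0.15, SPL4 (AT1G53160.1) by 0.62 ± 0.11, SPL10 (AT1G27370.4) by 0.35 ± 0.04 and SPL15 (AT3G57920.1) by 0.28 ± 0.08 (adjusted p = 0.128 without 8wk_LD_4wk_V replicate 4, 1 of 15 such arrays), whereas SPL3 (AT2G33810.1) fell by 0.90 ± 0.14. SOC1 (AT2G45660.1) was at 0.48 ± 0.14 (adjusted p = 0.0299 without 2wk_LD_4wk_V replicate 1, 1 of 3 such arrays), main adjusted p = 0.0597, and LFY (AT5G61850.1) at 0.26 ± 0.09 (adjusted p = 0.0223 without 2wk_LD_4wk_V replicate 4), main adjusted p = 0.119, neither past the test. Nor did FT (AT1G65480.1) at -0.03 ± 0.04, AP1 (AT1G69120.1) at -0.02 ± 0.05, SPL9 (AT2G42200.1) at 0.03 ± 0.06, VIN3 (AT5G57380.1) at 0.07 ± 0.12 and AP2 (AT4G36920.1) at 0.03 ± 0.08 pass, and SVP (AT2G22540) had the same value on all arrays and was not tested.

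In the floral transition list 3 of 16 measured genes rose, 1 fell and 12 did not pass (6 and 1 adjusted over the list alone). The floral transition list was called up by camera (adjusted p = 0.0295, and 0.422 with an estimated correlation). For the floral transition list the call ended at adjusted p = 0.0771 without 8wk_LD_4wk_V replicate 1, 0.0650 without 8wk_LD_4wk_V replicate 4 and 0.0567 within scan day 2. In the SPL family 4 of 11 measured genes rose, 1 fell and 6 did not pass (5 and 1 adjusted over the list alone). The SPL family was called up by camera (adjusted p = 0.00782, and 0.414 with an estimated correlation). The FLC clade and vernalization pathway list was not called, and after FLC its smallest adjusted p values belonged to VIP4 (AT5G61150.2), a gene of the Paf1 complex, which rose by 0.37 ± 0.06, and the Polycomb gene SWN (AT4G02020.1), which rose by 0.23 ± 0.04. Of the floral organ identity genes, SEP2 (AT3G02310.1) fell by 0.60 ± 0.08.

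**Figure D2:**
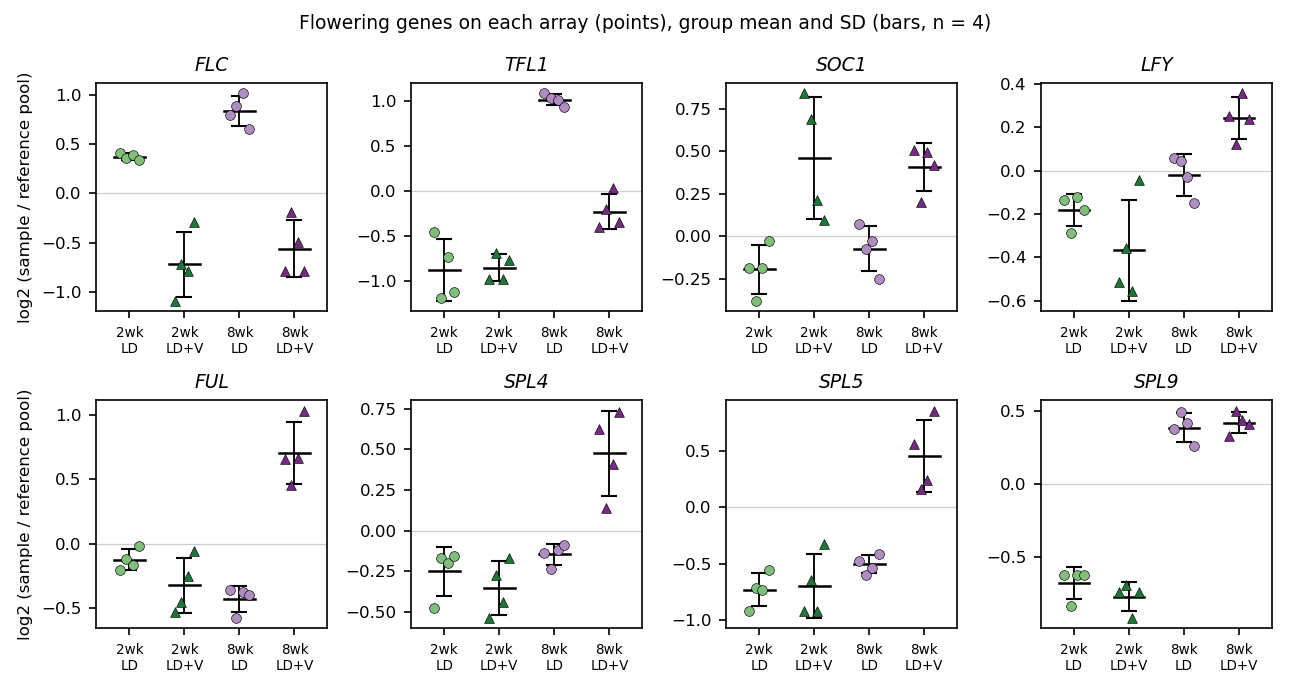
Deposited log2 ratio of sample to reference pool for 8 flowering genes, with 1 point per array, and bars for the mean and SD of each group (n = 4). FUL, SPL4 and SPL5 were highest in 8wk_LD_4wk_V, FLC was lower after vernalization at both ages, and TFL1 was highest in 8wk_LD.

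In the salicylate and jasmonate defence list 0 of 11 measured genes rose, 8 fell and 3 did not pass (0 and 8 adjusted over the list alone), and camera called it down (adjusted p = 2.21e-10, and 0.00178 with an estimated correlation). VSP2 (AT5G24770.2), a jasmonate-responsive storage protein, fell by 4.30 ± 0.39, the pathogenesis-related genes PR5 (AT1G75040.1) and PR2 (AT3G57260.1) fell by 2.13 ± 0.11 and by 1.37 ± 0.24, and ICS1 (AT1G74710.1), needed for salicylate synthesis, fell by 0.39 ± 0.07. In the cold acclimation list 4 of 27 measured genes rose, 0 fell and 23 did not pass (6 and 0 adjusted over the list alone). The cold acclimation list was called up by camera (adjusted p = 0.00376, and 0.422 with an estimated correlation). COR15B (AT2G42530.1), which encodes a cold-regulated chloroplast protein, rose by 3.56 ± 0.57, KIN2 (AT5G15970.1) by 1.07 ± 0.14, COR413IM1 (AT1G29395.1) by 0.68 ± 0.10 and the dehydrin gene RAB18 (AT5G66400.2) by 1.17 ± 0.27 (adjusted p = 0.0585 without 8wk_LD replicate 2, 1 of 3 such arrays).

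In the meristem and leaf primordium list 4 of 20 measured genes rose, 1 fell and 15 did not pass (4 and 1 adjusted over the list alone), and camera called it up (adjusted p = 0.0323, and 0.322 with an estimated correlation). For the meristem and leaf primordium list the call ended at adjusted p = 0.0621 without 8wk_LD replicate 3, 0.0771 without 8wk_LD_4wk_V replicate 1, 0.0539 without 8wk_LD_4wk_V replicate 4 and 0.0540 within scan day 2. STM (AT1G62360.1), which maintains the shoot meristem, rose by 0.79 ± 0.13, the YABBY gene FIL (AT2G45190.1) by 0.54 ± 0.10 and the boundary gene CUC3 (AT1G76420.1) by 0.39 ± 0.07. In the cell cycle and DNA replication list 0 of 31 measured genes rose, 2 fell and 29 did not pass (0 and 3 adjusted over the list alone), and camera called it down (adjusted p = 0.00139, and 0.422 with an estimated correlation). Its members past the test were the Aurora kinase gene AUR1 (AT4G32830.1), which fell by 0.45 ± 0.09, and CDKB2;2 (AT1G20930.1), which fell by 0.51 ± 0.11. In the trichome and stomatal lineage list 0 of 10 measured genes rose, 3 fell and 7 did not pass (0 and 3 adjusted over the list alone), and camera called it down (adjusted p = 0.0108, and 0.414 with an estimated correlation). Its medians on replicates 1 to 4 were -0.39, -0.03, -0.04 and -0.28 in 8wk_LD_4wk_V and -0.08, 0.07, -0.01 and -0.05 in 8wk_LD. The trichome initiation genes GL3 (AT5G41315.1) and GL1 (AT3G27920.1) fell by 1.1 ± 0.17 and by 0.91 ± 0.14, and GL2 (AT1G79840.1), which acts after them, fell by 0.74 ± 0.19 (adjusted p = 0.106 without 8wk_LD replicate 2, 1 of 5 such arrays).

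In the flavonoid and anthocyanin list 0 of 15 measured genes rose, 2 fell and 13 did not pass (0 and 3 adjusted over the list alone), and camera called it down (adjusted p = 0.0262, and 0.415 with an estimated correlation). For the flavonoid and anthocyanin list the call ended at adjusted p = 0.0578 without 8wk_LD replicate 3, 0.0519 without 8wk_LD replicate 4, 0.0535 without 8wk_LD_4wk_V replicate 2 and 0.0567 within scan day 2. CHS (AT5G13930.1), the entry enzyme of the pathway, fell by 1.93 ± 0.25, and the flavonol synthase gene FLS1 (AT5G08640.1) fell by 0.96 ± 0.24 (adjusted p = 0.0957 without 8wk_LD replicate 2, 1 of 6 such arrays). In the heat shock list 2 of 7 measured genes rose, 0 fell and 5 did not pass (5 and 0 adjusted over the list alone). The heat shock list was called up by camera (adjusted p = 0.000532, and 0.379 with an estimated correlation). HSP18.2 (AT5G59720.1) rose by 1.00 ± 0.22 and HSP90.1 (AT5G52640.1) by 1.1 ± 0.30 (adjusted p = 0.126 without 8wk_LD_4wk_V replicate 4, 1 of 12 such arrays), and the list medians on the arrays of 8wk_LD_4wk_V were -0.14, -0.22, 0.76 and 0.73 for replicates 1 to 4. Outside the lists called, GASA4 (AT5G15230.1), a gibberellin-regulated gene, fell by 1.25 ± 0.15, and GA3OX1 (AT1G15550.1), of gibberellin synthesis, rose by 0.52 ± 0.14 (adjusted p = 0.143 without 8wk_LD replicate 2, 1 of 11 such arrays). XCP1 (AT4G35350.2), a xylem protease gene, fell by 0.69 ± 0.15, and CYP83B1 (AT4G31500.1), of glucosinolate synthesis, fell by 0.81 ± 0.20 (adjusted p = 0.0896 without 8wk_LD replicate 2, 1 of 6 such arrays). The photoreceptor gene PHYB (AT2G18790.1) rose by 0.55 ± 0.14 (adjusted p = 0.0772 without 8wk_LD replicate 3, 1 of 5 such arrays) and the clock gene PRR5 (AT5G24470.1) fell by 0.47 ± 0.13 (adjusted p = 0.141 without 8wk_LD replicate 2, 1 of 12 such arrays). The gene models with the largest changes outside the lists were AT2G33830.2, which rose by 3.19 ± 0.40, and AT5G24780.1, which fell by 5.70 ± 0.49.

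The other lists were not called by camera. In the floral organ identity list 0 rose and 1 fell of 10 genes (adjusted p = 0.788). In the FLC clade and vernalization pathway list 2 rose and 1 fell of 20 genes (adjusted p = 0.131). In the AP2-like list 0 rose and 0 fell of 5 genes (adjusted p = 0.753). In the photoperiod and clock list 1 rose and 1 fell of 24 genes (adjusted p = 0.138, 0.0354 without 8wk_LD_4wk_V replicate 1, 0.0491 without 2wk_LD_4wk_V replicates 3 and 4). In the photosynthesis list 0 rose and 0 fell of 30 genes (adjusted p = 0.669). In the gibberellin list 1 rose and 1 fell of 26 genes (adjusted p = 0.902). In the glucosinolate list 0 rose and 1 fell of 9 genes (adjusted p = 0.250, 0.0377 without 8wk_LD_4wk_V replicates 2 and 3). In the vascular list 0 rose and 1 fell of 9 genes (adjusted p = 0.120, 0.0223 without 8wk_LD replicate 2, 0.0137 without 8wk_LD_4wk_V replicate 2, 0.00176 without 8wk_LD_4wk_V replicates 2 and 3). Adjusted over the list alone, the counts were 3 up and 2 down for the FLC clade and vernalization pathway list, 2 up and 1 down for the gibberellin list and 0 up and 2 down for the vascular list, and the same for the rest. Median, mean and test differed in sign for the floral organ identity list (median 0.04, mean -0.02, test up) and gibberellin list (median -0.00353, mean -0.02, test up).

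Over all features, 7700 of 169479 probes passed the limma test at an adjusted p of 0.05, 4216 higher and 3484 lower in 8wk_LD_4wk_V than in 8wk_LD, of which 279 and 651 changed at least 2-fold. Among 27553 Arabidopsis gene models, 906 rose and 810 fell. With scan day as a block the counts were 6087 probes and 1370 gene models, with 9 of 17 lists called, and among the arrays of scan day 2 alone they were 4527, 1043 and 6. Median centring of each array in place of loess left 55 probes, no background subtraction gave 15913, Agilent processed signals gave 12319, and leaving out 8wk_LD replicate 2 left 4586 probes and 1005 gene models. With 8wk_LD_4wk_V replicates 3 and 4 left out, a choice made after the values were seen, the counts were 2842 and 644, and without 8wk_LD_4wk_V replicates 2 and 3 the flavonoid and anthocyanin call ended (adjusted p = 0.114) and without 8wk_LD_4wk_V replicates 3 and 4 the floral transition, cold acclimation, flavonoid and anthocyanin, cell cycle and DNA replication and meristem and leaf primordium calls ended (adjusted p = 0.0900, 0.179, 0.0786, 0.452 and 0.0786). Fewer probes rose than fell without 8wk_LD replicate 4 (2811 and 3548), without 8wk_LD_4wk_V replicate 2 (3570 and 4282), without background subtraction (7031 and 8882) and with the Cy5 channel alone (3194 and 4286), as did gene models without these arrays (588 and 786, 801 and 955) or 8wk_LD_4wk_V replicate 3 (614 and 629).

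The comparison of 2wk_LD_4wk_V with 2wk_LD puts the same cold on plants that, per the labels, are too young to be induced. FLC fell by 1.09 ± 0.15 and SOC1, an integrator of flowering signals, rose by 0.65 ± 0.14. FUL was at -0.20 ± 0.11, TFL1 at 0.03 ± 0.14 and LFY at -0.19 ± 0.09 (adjusted p = 0.00934 without 2wk_LD_4wk_V replicate 4), none of them past the test. The SPL genes gave SPL3 at -0.09 ± 0.14, SPL4 at -0.10 ± 0.11, SPL5 at 0.03 ± 0.15, SPL9 at -0.09 ± 0.06 and SPL15 at -0.02 ± 0.08, and none of the 11 measured members of the family passed. FT, AP1 and AP2 lay between -0.07 and 0.01 and VIN3 at 0.26 ± 0.12 (adjusted p = 0.0315 without 2wk_LD_4wk_V replicate 3) and did not pass. VIP4 rose by 0.35 ± 0.06 and SWN by 0.19 ± 0.04, and of the floral organ identity genes AGL6 (AT2G45650.1) fell by 0.15 ± 0.03.

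Of the cold acclimation genes, COR15B rose by 4.67 ± 0.57 and RAB18 by 3.06 ± 0.27. COR413IM1 rose by 0.89 ± 0.10 and P5CS1 (AT2G39800.2), of proline synthesis, by 0.72 ± 0.12. In the cold acclimation list 11 of 27 measured genes rose, 0 fell and 16 did not pass (14 and 1 adjusted over the list alone). The cold acclimation list was called up by camera (adjusted p = 6.16e-06, and 0.322 with an estimated correlation). The list medians on the arrays of 2wk_LD_4wk_V were 0.53, 0.29, -0.07 and 0.01 for replicates 1 to 4. In the photoperiod and clock list 6 of 24 measured genes rose, 0 fell and 18 did not pass (8 and 1 adjusted over the list alone). The photoperiod and clock list was called up by camera (adjusted p = 0.0220, and 0.415 with an estimated correlation). The array medians of this list in the same order were 0.24, 0.11, -0.01 and 0.03. PHYB rose by 0.74 ± 0.14, CDF3 (AT3G47500.1) by 0.69 ± 0.14 and GI (AT1G22770.1), a clock gene that promotes flowering in long days, by 1.22 ± 0.31 (adjusted p = 0.0535 without 2wk_LD replicate 2).

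In the cell cycle and DNA replication list 0 of 31 measured genes rose, 14 fell and 17 did not pass (0 and 18 adjusted over the list alone), and camera called it down (adjusted p = 3.69e-09, and 0.271 with an estimated correlation). AUR1 fell by 1.1 ± 0.09, CYCB2;1 (AT2G17620.1) by 0.56 ± 0.07, CYCB1;2 (AT5G06150.1) by 0.51 ± 0.07 and CYCB2;2 (AT4G35620.1) by 0.54 ± 0.08. In the vascular list 0 of 9 measured genes rose, 6 fell and 3 did not pass (0 and 6 adjusted over the list alone). The vascular list was called down by camera (adjusted p = 2.75e-05, and 0.349 with an estimated correlation). XCP1 fell by 1.5 ± 0.15, XCP2 (AT1G20850.1) by 1.16 ± 0.20, and the secondary wall cellulose synthase genes CESA8 (AT4G18780.1) and CESA7 (AT5G17420.1) by 0.72 ± 0.09 and by 0.65 ± 0.09.

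The defence regulator EDS1 (AT3G48090.2) rose by 0.82 ± 0.10 and the defensin gene PDF1.2A (AT5G44420.1) by 1.26 ± 0.33, the only members of their list past the test. HSC70-1 (AT5G02500.1) rose by 0.69 ± 0.12, the DELLA genes RGL3 (AT5G17490.1) and RGL2 (AT3G03450.1) by 0.40 ± 0.10 and by 0.27 ± 0.06, and AIL6 (AT5G10510.1) by 0.22 ± 0.07 (adjusted p = 0.0956 without 2wk_LD replicate 1, 1 of 3 such arrays). GL3 fell by 0.99 ± 0.17, GL1 by 0.56 ± 0.14, GSTF12 (AT5G17220.1), needed for anthocyanin accumulation, by 0.59 ± 0.12, ANT (AT4G37750.1), which promotes organ growth, by 0.49 ± 0.16 (adjusted p = 0.136 without 2wk_LD replicate 1, 1 of 11 such arrays), and RBCS3B (AT5G38410.2), a Rubisco small subunit gene, by 0.76 ± 0.11. The photosynthesis medians on 2wk_LD_4wk_V replicates 1 to 4 were 0.39, 0.32, 0.01 and 0.04. Outside the lists, AT3G44020.1 rose by 5.28 ± 0.23, AT4G11310.1 fell by 2.39 ± 0.27 and AT2G16060.1 fell by 2.13 ± 0.16. No call was made for the other lists. In the floral transition list 1 rose and 0 fell of 16 genes (adjusted p = 0.788). In the floral organ identity list 0 rose and 1 fell of 10 genes (adjusted p = 0.190). In the FLC clade and vernalization pathway list 5 rose and 1 fell of 20 genes (adjusted p = 0.198). In the SPL family 0 rose and 0 fell of 11 genes (adjusted p = 0.906). In the AP2-like list 0 rose and 0 fell of 5 genes (adjusted p = 0.814). In the flavonoid and anthocyanin list 0 rose and 2 fell of 15 genes (adjusted p = 0.153, 0.0154 without 2wk_LD_4wk_V replicates 1 and 2). In the photosynthesis list 1 rose and 3 fell of 30 genes (adjusted p = 0.622, 0.0154 without 2wk_LD_4wk_V replicates 1 and 2). In the meristem and leaf primordium list 1 rose and 1 fell of 20 genes (adjusted p = 0.901). In the gibberellin list 5 rose and 1 fell of 26 genes (adjusted p = 0.380, 0.0262 without 2wk_LD_4wk_V replicates 1 and 2). In the salicylate and jasmonate defence list 2 rose and 0 fell of 11 genes (adjusted p = 0.434). In the heat shock list 1 rose and 0 fell of 7 genes (adjusted p = 0.198, 0.0368 without 8wk_LD_4wk_V replicates 3 and 4). In the glucosinolate list 0 rose and 0 fell of 9 genes (adjusted p = 0.431). In the trichome and stomatal lineage list 0 rose and 2 fell of 10 genes (adjusted p = 0.221). Adjusted over the list alone, the counts were 0 up and 1 down for the flavonoid and anthocyanin list, 0 up and 3 down for the photosynthesis list and 0 up and 0 down for the meristem and leaf primordium list, and the same for the rest. Median, mean and test differed in sign for the floral transition list (median -0.02, mean 0.02, test down), AP2-like list (median -0.05, mean -0.01, test up), photosynthesis list (median -0.04, mean 0.01, test down) and meristem and leaf primordium list (median 0.01, mean -0.01, test up).

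In all, 22658 of 169479 probes passed the limma test at an adjusted p of 0.05, 12037 higher and 10621 lower in 2wk_LD_4wk_V than in 2wk_LD, of which 951 and 463 changed at least 2-fold. Among 27553 Arabidopsis gene models, 2662 rose and 2455 fell. With scan day as a block the counts were 18362 probes and 4185 gene models, with 4 of 17 lists called, and among the arrays of scan day 2 alone they were 15545, 3548 and 4. Median centring in place of loess left 977 probes, and without 2wk_LD_4wk_V replicates 1 and 2 the photoperiod and clock call ended (adjusted p = 0.0989).

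The responses to vernalization at the 2 ages were set side by side. FLC, VIP4, SWN, COR15B, RAB18 and COR413IM1 changed in the same direction at both ages, as did AUR1, XCP1, GL1, GL3 and GASA4, which fell by 0.54 ± 0.15 (adjusted p = 0.0778 without 2wk_LD replicate 2, 1 of 4 such arrays) at 2 weeks. Of the gene models past the test, 418 rose at both ages against 87.5 by chance, 279 fell at both against 72.2, 25 rose at 8 weeks and fell at 2 weeks against 80.7, and 37 did the opposite against 78.3. Across the 169479 probes, which are not independent replicates, the log2 fold changes correlated with r = 0.381 and rho = 0.316, and across gene models with r = 0.361 and rho = 0.338. With scan day as a block r was 0.384 across probes, and among the arrays of scan day 2 it was 0.361. Without 8wk_LD_4wk_V replicates 3 and 4 it was 0.262.

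The interaction is the vernalization effect at 8 weeks minus that at 2 weeks. Both include 4 more weeks of age and short days, so it does not isolate the cold. FUL had an interaction of 1.33 ± 0.16, FD of 0.70 ± 0.12 and TFL1 of -1.27 ± 0.19. The SPL genes past the test were SPL10 at 0.30 ± 0.06, SPL5 at 0.93 ± 0.21 (adjusted p = 0.0558 without 8wk_LD replicate 2, 1 of 2 such arrays), SPL4 at 0.72 ± 0.16 (adjusted p = 0.0545 without 8wk_LD replicate 2, 1 of 3 such arrays) and SPL3 at -0.81 ± 0.19 (adjusted p = 0.0660 without 8wk_LD replicate 2, 1 of 7 such arrays). For FLC, which fell at both ages, the difference of -0.31 ± 0.21 did not pass. LFY at 0.45 ± 0.13 (adjusted p = 0.00604 without 2wk_LD_4wk_V replicate 4), main adjusted p = 0.0716, did not pass either. SOC1, SPL9, FT, AP1, VIN3 and AP2 lay between -0.19 and 0.13 and SPL15 at 0.30 ± 0.11 (adjusted p = 0.0403 without 8wk_LD_4wk_V replicate 2), and none of them passed. In the SPL family 3 of 11 measured genes had a positive interaction past the test, 1 a negative one and 7 neither (4 and 1 adjusted over the list alone). Camera called it up (adjusted p = 0.0254, and 0.422 with an estimated correlation). For the SPL family the call ended at adjusted p = 0.0555 without 2wk_LD replicate 4, 0.0788 without 2wk_LD_4wk_V replicate 1, 0.0720 without 8wk_LD replicate 1 and 0.0562 without 8wk_LD_4wk_V replicate 4. Of the floral organ identity genes, AGL6 was at 0.22 ± 0.05 and SEP2 at -0.45 ± 0.11 (adjusted p = 0.0678 without 2wk_LD replicate 2, 1 of 8 such arrays).

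Of the 17 lists, that of defence genes had the interaction median farthest from 0, at -1.18. In the salicylate and jasmonate defence list 0 of 11 measured genes had a positive interaction past the test, 6 a negative one and 5 neither (0 and 8 adjusted over the list alone), and camera called it down (adjusted p = 6.29e-10, and 0.00178 with an estimated correlation). PR5 was at -1.87 ± 0.16, EDS1 at -1.18 ± 0.14, VSP2 at -3.60 ± 0.56 and PR2 at -1.91 ± 0.34. In the cold acclimation list 0 of 27 measured genes had a positive interaction past the test, 3 a negative one and 24 neither (0 and 3 adjusted over the list alone). Camera called it down (adjusted p = 0.0182, and 0.501 with an estimated correlation). For the cold acclimation list the call ended at adjusted p = 0.0949 without 2wk_LD_4wk_V replicate 1, 0.0653 without 2wk_LD_4wk_V replicate 2 and 0.0638 without 8wk_LD replicate 4. RAB18 was at -1.89 ± 0.38, P5CS1 at -0.72 ± 0.17 (adjusted p = 0.0675 without 2wk_LD replicate 2, 1 of 9 such arrays) and GOLS2 (AT1G56600.1), of galactinol synthesis, at -1.31 ± 0.34 (adjusted p = 0.0915 without 8wk_LD_4wk_V replicate 1, 1 of 11 such arrays), and the medians of this list on 2wk_LD_4wk_V replicates 1 to 4 were 0.53, 0.29, -0.07 and 0.01. In the cell cycle and DNA replication list 2 of 31 measured genes had a positive interaction past the test, 0 a negative one and 29 neither (8 and 0 adjusted over the list alone), and camera called it up (adjusted p = 0.000133, and 0.414 with an estimated correlation). AUR1 was at 0.64 ± 0.13 and CYCB2;1 at 0.41 ± 0.11 (adjusted p = 0.0937 without 2wk_LD replicate 2, 1 of 13 such arrays). In the vascular list 3 of 9 measured genes had a positive interaction past the test, 0 a negative one and 6 neither (5 and 0 adjusted over the list alone). The vascular list was called up by camera (adjusted p = 0.000485, and 0.414 with an estimated correlation). CESA8 was at 0.63 ± 0.13, CESA7 at 0.59 ± 0.12 and XCP1 at 0.81 ± 0.21 (adjusted p = 0.0872 without 2wk_LD replicate 2, 1 of 11 such arrays). Elsewhere CHS was at -1.59 ± 0.35, RBCS3B at 0.71 ± 0.15, FIL at 0.59 ± 0.14 (adjusted p = 0.0588 without 2wk_LD replicate 1, 1 of 3 such arrays) and CYP83B1 at -1.09 ± 0.28 (adjusted p = 0.0983 without 8wk_LD replicate 2, 1 of 13 such arrays). Outside the lists, AT5G05250.1 was at 4.29 ± 0.33, AT3G30775.1 at 3.05 ± 0.52, AT5G24780.1 at -4.26 ± 0.70 and AT2G43570.1 at -4.01 ± 0.55.

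Camera made no interaction call for the other lists. In the floral transition list 2 of 16 genes had a positive and 1 a negative one (adjusted p = 0.0846, 0.0372 without 2wk_LD replicate 2, 0.0365 without 2wk_LD_4wk_V replicate 4, 0.0237 without 8wk_LD_4wk_V replicate 2, 0.0132 without 8wk_LD_4wk_V replicates 2 and 3). In the floral organ identity list 1 of 10 genes had a positive and 1 a negative one (adjusted p = 0.221). In the FLC clade and vernalization pathway list 0 of 20 genes had a positive and 0 a negative one (adjusted p = 0.813). In the AP2-like list 0 of 5 genes had a positive and 0 a negative one (adjusted p = 0.665). In the photoperiod and clock list 0 of 24 genes had a positive and 0 a negative one (adjusted p = 0.219, 0.0444 without 8wk_LD_4wk_V replicates 2 and 3). In the flavonoid and anthocyanin list 0 of 15 genes had a positive and 1 a negative one (adjusted p = 0.713). In the photosynthesis list 1 of 30 genes had a positive and 0 a negative one (adjusted p = 0.390, 0.00428 without 2wk_LD_4wk_V replicates 1 and 2). In the meristem and leaf primordium list 1 of 20 genes had a positive and 0 a negative one (adjusted p = 0.118, 0.0369 without 8wk_LD_4wk_V replicates 2 and 3). In the gibberellin list 0 of 26 genes had a positive and 0 a negative one (adjusted p = 0.338, 0.0207 without 2wk_LD_4wk_V replicates 1 and 2). In the heat shock list 0 of 7 genes had a positive and 0 a negative one (adjusted p = 0.203, 0.0461 without 8wk_LD_4wk_V replicate 1, 0.0237 without 8wk_LD_4wk_V replicate 2). In the glucosinolate list 0 of 9 genes had a positive and 1 a negative one (adjusted p = 0.124, 0.0430 without 2wk_LD_4wk_V replicate 4, 0.0439 without 8wk_LD_4wk_V replicate 2, 0.0224 without 8wk_LD_4wk_V replicates 2 and 3, 0.0117 without 2wk_LD_4wk_V replicates 3 and 4). In the trichome and stomatal lineage list 0 of 10 genes had a positive and 0 a negative one (adjusted p = 0.366, 0.0313 without 8wk_LD_4wk_V replicates 2 and 3). Adjusted over the list alone, the counts were 3 positive and 1 negative for the floral transition list and 0 positive and 1 negative for the heat shock list, and the same for the rest. Median, mean and test differed in sign for the AP2-like list (median 0.05, mean -0.00302, test down).

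Past the test stood 4138 of 169479 probes, 1733 positive and 2405 negative, and 1097 of 27553 gene models, 501 positive and 596 negative. With scan day as a block the counts were 3476 probes and 920 gene models, with 5 of 17 lists called, and among the arrays of scan day 2 alone they were 1924, 514 and 5. Leaving out 2wk_LD replicate 2, 2wk_LD replicate 3 or 8wk_LD replicate 2 left 2427, 2708 or 2514 probes and 686, 713 or 627 gene models, and median centring in place of loess left 39 probes. Leaving out 2wk_LD_4wk_V replicates 3 and 4 gave 8787 probes, no background subtraction gave 11062, the Cy5 channel alone gave 6873, and without 8wk_LD_4wk_V replicates 3 and 4 the SPL family call ended (adjusted p = 0.0859) and without 2wk_LD_4wk_V replicates 1 and 2 the SPL family and cold acclimation calls ended (adjusted p = 0.161 and 0.754). Without 8wk_LD_4wk_V replicate 4 there were more positive than negative probes (1968 and 1928) and gene models (558 and 469).

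The comparison of 8wk_LD with 2wk_LD asks what differs between apices that are competent to respond and those that are not, before any cold. TFL1 was higher at 8 weeks by 1.89 ± 0.14. PNY (AT5G02030.1), a homeobox gene of inflorescence development, was higher by 0.78 ± 0.10 and FD by 0.31 ± 0.08. SPL9, which promotes the adult phase, was higher by 1.07 ± 0.06, SPL13 (AT5G50570.2) by 0.95 ± 0.10, SPL3 by 0.94 ± 0.14, SPL10 by 0.67 ± 0.04 and SPL6 (AT1G69170.1) by 0.52 ± 0.05. The floral repressors SMZ (AT3G54990.1) and SNZ (AT2G39250.1), targets of miR172, fell by 1.42 ± 0.22 and by 1.1 ± 0.11, and TOE3 (AT5G67180.1) rose by 0.33 ± 0.06. FLC rose by 0.46 ± 0.15 (adjusted p = 0.0984 without 8wk_LD replicate 3, 1 of 7 such arrays). Not past the test were SPL4 at 0.10 ± 0.11, SPL5 at 0.22 ± 0.15, SPL15 at 0.08 ± 0.08, SOC1 at 0.12 ± 0.14, LFY at 0.16 ± 0.09 and FUL at -0.30 ± 0.11 (adjusted p = 0.0269 without 8wk_LD_4wk_V replicate 4, 1 of 3 such arrays). FT, AP1, VIN3 and AP2 lay between -0.08 and 0.08 and did not pass.

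In the SPL family 7 of 11 measured genes rose, 0 fell and 4 did not pass (7 and 0 adjusted over the list alone). The SPL family was called up by camera (adjusted p = 6.09e-07, and 0.179 with an estimated correlation). In the FLC clade and vernalization pathway list 5 of 20 measured genes rose, 1 fell and 14 did not pass (5 and 1 adjusted over the list alone), and camera called it up (adjusted p = 0.0355, and 0.422 with an estimated correlation). For the FLC clade and vernalization pathway list the call ended at adjusted p = 0.0516 without 2wk_LD replicate 2, 0.0532 without 2wk_LD replicate 4 and 0.0682 without 8wk_LD replicate 1. VIP4 rose by 0.42 ± 0.06, VRN1 (AT3G18990.1), needed for stable repression of FLC after cold in Arabidopsis, by 0.50 ± 0.10, and FRI (AT4G00650.1), which raises FLC there, by 0.23 ± 0.05. In the meristem and leaf primordium list 8 of 20 measured genes rose, 1 fell and 11 did not pass (8 and 2 adjusted over the list alone), and camera called it up (adjusted p = 0.0294, and 0.322 with an estimated correlation). CUC1 (AT3G15170.1) rose by 0.51 ± 0.11, AIL6 by 0.30 ± 0.07 and KNAT2 (AT1G70510.1) by 0.28 ± 0.06, whereas ATML1 (AT4G21750.2), an epidermal homeobox gene, fell by 0.41 ± 0.10. In the cell cycle and DNA replication list 10 of 31 measured genes rose, 2 fell and 19 did not pass (12 and 2 adjusted over the list alone), and camera called it up (adjusted p = 0.0274, and 0.566 with an estimated correlation). For the cell cycle and DNA replication list the call ended at adjusted p = 0.0695 without 8wk_LD replicate 1 and 0.0514 within scan day 2. CYCA1;1 (AT1G44110.1) rose by 0.63 ± 0.07 and MCM4 (AT2G16440.1) by 0.21 ± 0.05, and CYCB2;1 fell by 0.30 ± 0.07.

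In the photosynthesis list 0 of 30 measured genes rose, 19 fell and 11 did not pass (0 and 21 adjusted over the list alone), and camera called it down (adjusted p = 1.82e-09, and 0.322 with an estimated correlation). GAPB (AT1G42970.1), PRK (AT1G32060.1) and SBPASE (AT3G55800.1), of the Calvin cycle, fell by 1.74 ± 0.15, by 1.39 ± 0.14 and by 1.34 ± 0.11, and RBCS3B fell by 1.54 ± 0.11. In the glucosinolate list 0 of 9 measured genes rose, 6 fell and 3 did not pass (0 and 6 adjusted over the list alone). The glucosinolate list was called down by camera (adjusted p = 0.00127, and 0.349 with an estimated correlation). CYP83A1 (AT4G13770.1) and CYP79F1 (AT1G16410.1), of the aliphatic branch, fell by 2.86 ± 0.29 and fell by 2.74 ± 0.30, and their regulators MYB29 (AT5G07690.1) and MYB28 (AT5G61420.2) by 1.06 ± 0.19 and by 0.60 ± 0.10. In the vascular list 0 of 9 measured genes rose, 7 fell and 2 did not pass (0 and 8 adjusted over the list alone). The vascular list was called down by camera (adjusted p = 6.09e-07, and 0.322 with an estimated correlation). XCP1 fell by 2.19 ± 0.15, XCP2 by 1.71 ± 0.20, CESA8 by 0.92 ± 0.09 and CESA7 by 0.83 ± 0.09.

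In the salicylate and jasmonate defence list 7 of 11 measured genes rose, 0 fell and 4 did not pass (8 and 0 adjusted over the list alone), and camera called it up (adjusted p = 2.87e-05, and 0.0315 with an estimated correlation). VSP2 rose by 3.62 ± 0.39, PAD4 (AT3G52430.1) by 1.75 ± 0.19, PR5 by 1.25 ± 0.11 and EDS1 by 0.99 ± 0.10. CHS rose by 2.57 ± 0.25 and FLS1 by 1.74 ± 0.24, while UGT75C1 (AT4G14090.1), an anthocyanin glucosyltransferase gene, fell by 0.30 ± 0.07. The clock gene ELF4 (AT2G40080.1) fell by 1.85 ± 0.28 and PHYB rose by 0.85 ± 0.14. GASA4 fell by 1.06 ± 0.15 and CPS (AT4G02780.1), the entry enzyme of gibberellin synthesis, by 0.28 ± 0.05, and the DELLA gene GAI (AT1G14920.1) rose by 0.82 ± 0.15. P5CS1 rose by 0.75 ± 0.12, CBF3 (AT4G25480.1) by 0.26 ± 0.07, HSC70-1 by 0.54 ± 0.12 and SEP2 by 0.42 ± 0.08, and CRC (AT1G69180.1) fell by 0.16 ± 0.04 and the stomatal gene EPF2 (AT1G34245.1) by 0.58 ± 0.13. Outside the lists, AT5G24780.1 rose by 4.33 ± 0.49, AT1G58260.1 fell by 4.27 ± 0.40 and AT5G05250.1 fell by 3.84 ± 0.23. Camera did not call the rest of the lists. In the floral transition list 4 rose and 0 fell of 16 genes (adjusted p = 0.0784, 0.0390 without 2wk_LD replicate 1, 0.0432 within scan day 2). In the floral organ identity list 1 rose and 3 fell of 10 genes (adjusted p = 0.250). In the AP2-like list 1 rose and 2 fell of 5 genes (adjusted p = 0.4). In the photoperiod and clock list 2 rose and 3 fell of 24 genes (adjusted p = 0.814). In the cold acclimation list 3 rose and 1 fell of 27 genes (adjusted p = 0.609). In the flavonoid and anthocyanin list 2 rose and 2 fell of 15 genes (adjusted p = 0.665). In the gibberellin list 4 rose and 6 fell of 26 genes (adjusted p = 0.378). In the heat shock list 1 rose and 0 fell of 7 genes (adjusted p = 0.240). In the trichome and stomatal lineage list 0 rose and 4 fell of 10 genes (adjusted p = 0.0673, 0.0254 without 8wk_LD replicate 2, 0.0442 without 8wk_LD_4wk_V replicate 2, 0.0497 without 8wk_LD_4wk_V replicate 4, 0.0307 without 8wk_LD_4wk_V replicates 2 and 3, 0.0468 without 8wk_LD_4wk_V replicates 3 and 4). Adjusted over the list alone, the counts were 2 up and 2 down for the photoperiod and clock list and 3 up and 0 down for the cold acclimation list, and the same for the rest. Median, mean and test differed in sign for the photoperiod and clock list (median 0.01, mean -0.04, test down).

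Across the array, 32411 of 169479 probes passed the limma test at an adjusted p of 0.05, 16144 higher and 16267 lower in 8wk_LD than in 2wk_LD, of which 1249 and 2771 changed at least 2-fold. Among 27553 Arabidopsis gene models, 3575 rose and 3641 fell. With scan day as a block the counts were 31423 probes and 6996 gene models, with 8 of 17 lists called, and among the arrays of scan day 2 alone they were 22441, 5179 and 8. Median centring in place of loess left 5331 probes, 15.4% of them higher at 8 weeks against 49.8%, a share that ran from 47.3% (without 8wk_LD replicate 1) to 54.6% (without 8wk_LD replicate 4) with 1 array left out.

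The comparison of 8wk_LD_4wk_V with 2wk_LD_4wk_V contrasts plants that the same cold did and, per the labels, did not induce. FUL was higher in the older plants by 1.03 ± 0.11, FD by 1.01 ± 0.08, PNY by 0.94 ± 0.10, TFL1 by 0.62 ± 0.14 and LFY, which confers floral meristem identity, by 0.61 ± 0.09. SPL9 was higher by 1.19 ± 0.06, SPL5 by 1.15 ± 0.15, SPL13 by 1.01 ± 0.10, SPL10 by 0.97 ± 0.04, SPL4 by 0.83 ± 0.11, SPL6 by 0.62 ± 0.05 and SPL15 by 0.38 ± 0.08. SMZ fell by 1.33 ± 0.22 and SNZ by 1.04 ± 0.11. FLC at 0.16 ± 0.15, SOC1 at -0.05 ± 0.14 and SPL3 at 0.13 ± 0.14 did not pass. FT, AP1 and VIN3 lay between -0.18 and -0.05 and AP2 at 0.18 ± 0.08 (adjusted p = 0.0150 without 2wk_LD_4wk_V replicate 3) and did not pass.

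In the floral transition list 8 of 16 measured genes rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone). The floral transition list was called up by camera (adjusted p = 0.000780, and 0.322 with an estimated correlation). In the SPL family 9 of 11 measured genes rose, 0 fell and 2 did not pass (9 and 0 adjusted over the list alone). The SPL family was called up by camera (adjusted p = 7.83e-10, and 0.0764 with an estimated correlation). In the meristem and leaf primordium list 9 of 20 measured genes rose, 2 fell and 9 did not pass (10 and 3 adjusted over the list alone), and camera called it up (adjusted p = 0.000812, and 0.147 with an estimated correlation). STM rose by 0.97 ± 0.13, FIL by 0.95 ± 0.10 and CUC1 by 0.86 ± 0.11. In the cell cycle and DNA replication list 16 of 31 measured genes rose, 0 fell and 15 did not pass (18 and 0 adjusted over the list alone), and camera called it up (adjusted p = 3.05e-08, and 0.314 with an estimated correlation). AUR1 rose by 0.67 ± 0.09, CYCA1;1 by 0.58 ± 0.07 and CYCB1;2 by 0.52 ± 0.07.

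In the glucosinolate list 0 of 9 measured genes rose, 8 fell and 1 did not pass (1 and 8 adjusted over the list alone). The glucosinolate list was called down by camera (adjusted p = 9.91e-06, and 0.259 with an estimated correlation). CYP79F1 fell by 3.70 ± 0.30, CYP83A1 by 2.34 ± 0.29 and MAM1 (AT5G23010.1), which elongates methionine side chains, by 1.53 ± 0.18. The medians of this list on 8wk_LD_4wk_V replicates 1 to 4 were -0.94, -0.29, -0.45 and -1.06. In the photosynthesis list 0 of 30 measured genes rose, 19 fell and 11 did not pass (0 and 22 adjusted over the list alone), and camera called it down (adjusted p = 1.71e-09, and 0.322 with an estimated correlation). GAPB fell by 1.52 ± 0.15, PRK by 1.15 ± 0.14, RBCS3B by 0.84 ± 0.11 and the light-harvesting gene LHCA2 (AT3G61470.1) by 0.79 ± 0.08. In the vascular list 0 of 9 measured genes rose, 5 fell and 4 did not pass (0 and 6 adjusted over the list alone). The vascular list was called down by camera (adjusted p = 0.00203, and 0.422 with an estimated correlation). SUC2 (AT1G22710.1), a phloem sucrose transporter gene, fell by 2.05 ± 0.32 and XCP1 by 1.37 ± 0.15. In the trichome and stomatal lineage list 0 of 10 measured genes rose, 5 fell and 5 did not pass (0 and 6 adjusted over the list alone), and camera called it down (adjusted p = 0.0108, and 0.414 with an estimated correlation). Its medians on 8wk_LD_4wk_V replicates 1 to 4 were -0.39, -0.03, -0.04 and -0.28. GL1 fell by 0.84 ± 0.14, EPF2 by 0.66 ± 0.13 and TMM (AT1G80080.1) by 0.33 ± 0.07.

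In the heat shock list 5 of 7 measured genes rose, 0 fell and 2 did not pass (5 and 0 adjusted over the list alone). The heat shock list was called up by camera (adjusted p = 0.0223, and 0.467 with an estimated correlation). For the heat shock list the call ended at adjusted p = 0.0595 without 8wk_LD_4wk_V replicate 3. HSP17.6II (AT5G12020.1) rose by 1.25 ± 0.34, HSP18.2 by 0.83 ± 0.22 and HSP17.6A (AT5G12030.1) by 0.46 ± 0.13. The medians on 8wk_LD_4wk_V replicates 1 to 4 were -0.14, -0.22, 0.76 and 0.73. The cold acclimation list was not called, and its members went both ways: SUS1 (AT5G20830.2), a sucrose synthase gene, rose by 0.82 ± 0.14 and KIN2 by 0.78 ± 0.14, while RAB18 fell by 1.66 ± 0.27 and GOLS2 by 1.24 ± 0.24. CHS rose by 0.98 ± 0.25 and FLS1 by 1.08 ± 0.24, UGT75C1 fell by 0.35 ± 0.07, and GASA4 and GASA1 (AT1G75750.1) fell by 1.77 ± 0.15 and by 0.57 ± 0.11. PR5 fell by 0.62 ± 0.11, PDF1.2A by 1.29 ± 0.33 and PR2 by 0.83 ± 0.24 (adjusted p = 0.0612 without 8wk_LD_4wk_V replicate 1, 1 of 3 such arrays), the members of the defence list past the test. VIP4 rose by 0.43 ± 0.06, ELF7 (AT1G79730.1) by 0.26 ± 0.05 and PHYB by 0.66 ± 0.14, and CDF1 (AT5G62430.1) fell by 0.60 ± 0.12 and CRC by 0.14 ± 0.04. Outside the lists, AT3G46230.1 (HSP17.4), also a heat shock gene, rose by 2.69 ± 0.66, with log2 ratios of -0.27, -0.94, 2.78 and 2.79 on 8wk_LD_4wk_V replicates 1 to 4. AT3G30775.1 rose by 2.56 ± 0.37 and AT3G54600.1 fell by 3.71 ± 0.16.

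**Figure D3:**
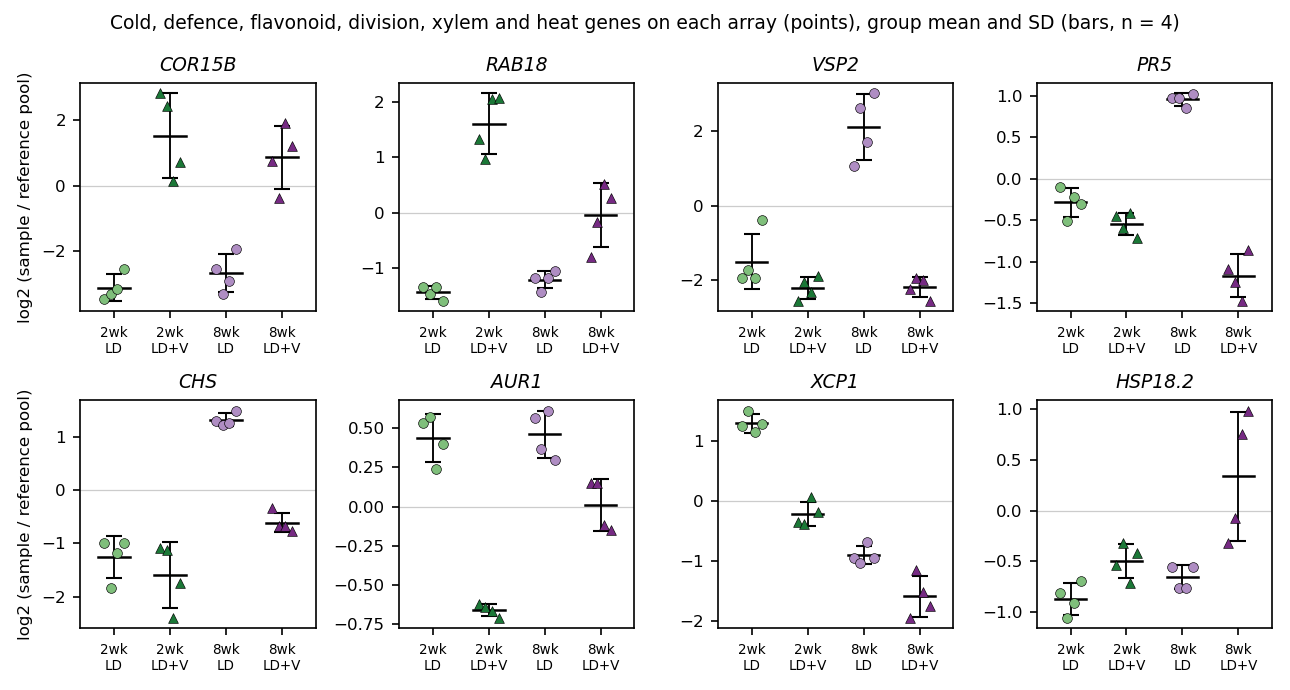
Deposited log2 ratio of sample to reference pool for 8 genes of the cold, defence, flavonoid, cell cycle, vascular and heat shock lists, with 1 point per array, and bars for the mean and SD of each group (n = 4). VSP2 and PR5 were highest in 8wk_LD, and HSP18.2 was highest on replicates 3 and 4 of 8wk_LD_4wk_V.

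The remaining lists were not called. In the floral organ identity list 1 rose and 1 fell of 10 genes (adjusted p = 0.925). In the FLC clade and vernalization pathway list 4 rose and 0 fell of 20 genes (adjusted p = 0.0631, 0.0349 without 2wk_LD_4wk_V replicate 3, 0.0497 without 8wk_LD_4wk_V replicate 4, 0.0325 without 2wk_LD_4wk_V replicates 3 and 4, 0.0398 with gene models chosen by SD). In the AP2-like list 0 rose and 2 fell of 5 genes (adjusted p = 0.219). In the photoperiod and clock list 1 rose and 3 fell of 24 genes (adjusted p = 0.157, 0.0384 without 8wk_LD_4wk_V replicates 2 and 3). In the cold acclimation list 3 rose and 8 fell of 27 genes (adjusted p = 0.120, 0.0137 without 2wk_LD_4wk_V replicate 3, 0.0467 without 8wk_LD_4wk_V replicate 3, 0.0146 without 8wk_LD_4wk_V replicates 3 and 4, 0.000676 without 2wk_LD_4wk_V replicates 3 and 4). In the flavonoid and anthocyanin list 3 rose and 1 fell of 15 genes (adjusted p = 0.661). In the gibberellin list 1 rose and 6 fell of 26 genes (adjusted p = 0.136, 0.00465 without 2wk_LD_4wk_V replicates 1 and 2). In the salicylate and jasmonate defence list 0 rose and 3 fell of 11 genes (adjusted p = 0.213). Adjusted over the list alone, the counts were 0 up and 1 down for the floral organ identity list, 2 up and 3 down for the AP2-like list and 4 up and 12 down for the cold acclimation list, and the same for the rest. Median, mean and test differed in sign for the floral organ identity list (median -0.01, mean -0.02, test up).

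For this pair of groups, 30986 of 169479 probes passed the limma test at an adjusted p of 0.05, 15206 higher and 15780 lower in 8wk_LD_4wk_V than in 2wk_LD_4wk_V, of which 739 and 3102 changed at least 2-fold. Among 27553 Arabidopsis gene models, 3569 rose and 3686 fell. With scan day as a block the counts were 29858 probes and 6964 gene models, with 9 of 17 lists called, and among the arrays of scan day 2 alone they were 28344, 6684 and 9. Median centring in place of loess left 3310 probes, 14.4% of them higher at 8 weeks against 49.1%, or 45.5% (without 8wk_LD_4wk_V replicate 2) to 52.8% (without 8wk_LD_4wk_V replicate 1) with 1 array left out, and a fit on these 2 groups alone left 17933 probes and 4383 gene models. Among the list calls, without 8wk_LD_4wk_V replicates 3 and 4 the heat shock call ended (adjusted p = 0.179), without 2wk_LD_4wk_V replicates 1 and 2 the trichome and stomatal lineage call ended (adjusted p = 0.107) and without 2wk_LD_4wk_V replicates 3 and 4 the heat shock call ended (adjusted p = 0.0788).

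**Figure D4:**
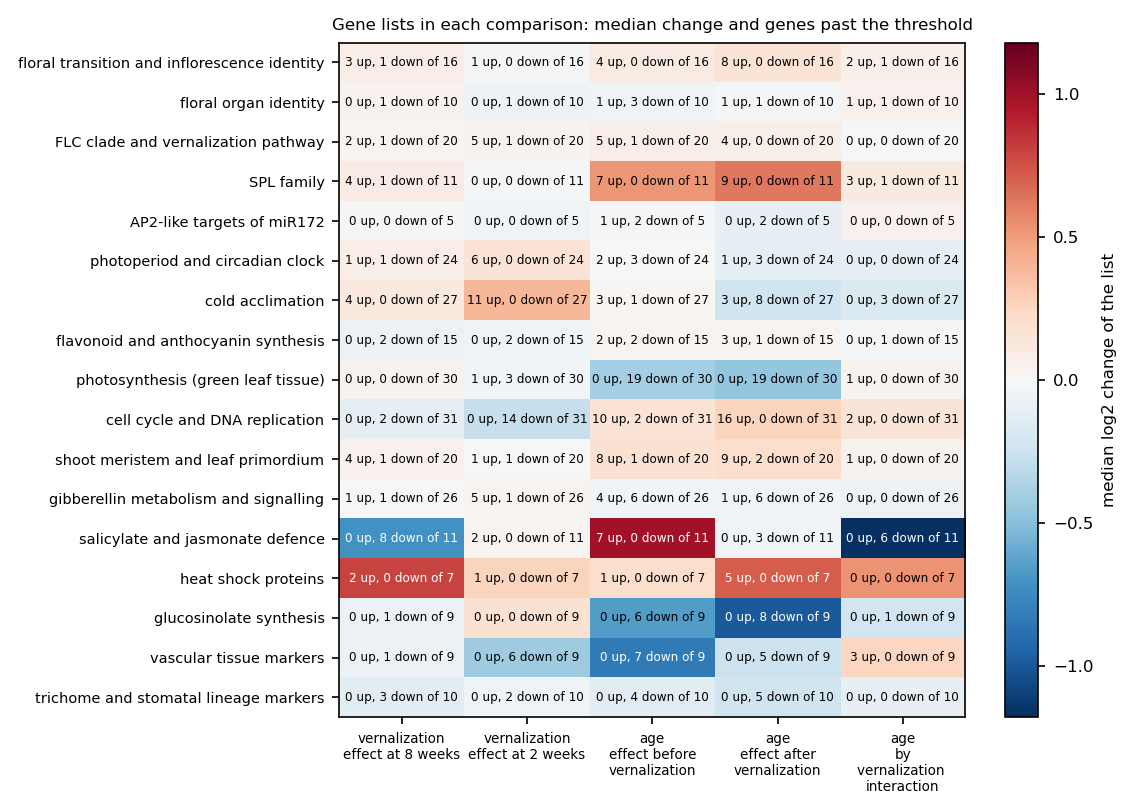
Median log2 fold change of the measured genes of 17 lists (color) in 5 comparisons, with the numbers past the test up and down. Camera called 35 of 85 list tests, 20 up and 15 down, and 3 with an estimated correlation, all for the defence list. These 3 are not independent, as all use 8wk_LD (mean median 0.38, others -0.32 to -0.11).

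Camera with its preset correlation of 0.01 also called lists under other splits of the arrays. Adjusted over the 17 lists of 1 comparison rather than over all 85 tests, the real grouping gave 9, 4, 8 and 10 calls in the 4 comparisons of groups, in the order of vernalization at 8 and 2 weeks and age before and after it, against at most 9, 7, 10 and 13 under the other splits, and for the interaction 5 against at most 10. As many calls arose in 2, 16, 5 and 3 of 35 splits, the real one included, and in 27 of 100 for the interaction.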

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

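The tests of the scanner protocol, of the share of leaf tissue and of other splits of the arrays were chosen after the results were seen, as was the measure of spread for the gap between correlations, whereas the bounds for normalization, harvest time and the second heat list were set before their results.

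On some arrays a value lay far from the other 3 of its group, with a gap close to the whole range of the group. This held in 30 of 412 groups of 4 values for the genes named here (7.28%), 5 of 68 for list medians and 2 of 28 for array measures, and chance gives about 1 in 20 groups (5%). Deposited values are rounded, so that 3 equal values are enough to set the other apart.

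In 2wk_LD, on replicate 1, CRC was 0.10 (others 0.16 to 0.18), VIP4 was -0.29 (others -0.49 to -0.47), SPL4 was -0.47 (others -0.20 to -0.15), CUC3 was -0.38 (others -0.22 to -0.20) and CESA7 was 0.21 (others 0.59 to 0.67). On replicate 2, SPL9 was -0.84 (others all at -0.62), CYCB2;2 was 0.53 (others 0.43 to 0.44), the median Cy5 background was 43 (others all at 42) and the median of the floral organ identity list was 0.063 (others all at 0.070). On replicate 3, the median of the cell cycle and DNA replication list was 0.070 (others all at 0.084). On replicate 4, VSP2 was -0.40 (others -1.94 to -1.74).

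In 2wk_LD_4wk_V, on replicate 1, SPL15 was -0.23 (others -0.15 to -0.14). On replicate 2, SWN was 0.014 (others all at 0.10), LHCA2 was 0.73 (others 0.36 to 0.40) and the median of the FLC clade and vernalization pathway list was -0.10 (others 0 to 0.0072). On replicate 3, FIL was -0.54 (others -0.15 to -0.14).

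In 8wk_LD, on replicate 1, RBCS3B was -1.22 (others -1 to -0.97) and ANT was 0.72 (others 0.34 to 0.40). On replicate 2, FUL was -0.58 (others -0.40 to -0.36), STM was -0.38 (others -0.044 to 0), RGL3 was 0.24 (others -0.074 to -0.044), MYB29 was -1.18 (others -0.62 to -0.56) and CYP83B1 was 0.20 (others -0.12 to -0.074). On replicate 4, SPL15 was -0.12 (others all at -0.059), SBPASE was -0.92 (others all at -0.74), FIL was -0.10 (others 0.25 to 0.30), GASA4 was 0.12 (others -0.49 to -0.40), PDF1.2A was 0.15 (others -0.69 to -0.58) and the median of the meristem and leaf primordium list was -0.029 (others all at 0.014).

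In 8wk_LD_4wk_V, on replicate 1, CDF3 was -0.32 (others -0.044 to 0) and the median of the gibberellin list was -0.051 (others -7.21e-05 to 0.0072). On replicate 2, KIN2 was 0.37 (others 0.81 to 0.85) and the number of spots marked as outliers was 1707 (others 85 to 167). On replicate 3, HSC70-1 was 0.38 (others -0.044 to -0.014). On replicate 4, TOE3 was 0.18 (others -0.029 to 0), ANT was -0.12 (others 0.32 to 0.36) and ATML1 was -0.42 (others -0.029 to 0.043).

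The response to vernalization differed between the 2 ages by the interaction test for FUL (1.33), FD (0.70), AGL6 (0.22), SPL4 (0.72), SPL5 (0.93), SPL10 (0.30), RBCS3B (0.71), CYCB2;1 (0.41), AUR1 (0.64), FIL (0.59), XCP1 (0.81), CESA7 (0.59) and CESA8 (0.63), which were more positive at 8 weeks. It also differed for TFL1 (-1.27), SEP2 (-0.45), SPL3 (-0.81), GOLS2 (-1.31), RAB18 (-1.89), P5CS1 (-0.72), CHS (-1.59), PR2 (-1.91), PR5 (-1.87), ICS1 (-0.42), PAD4 (-1.27), EDS1 (-1.18), VSP2 (-3.60) and CYP83B1 (-1.09), which were more negative at 8 weeks. For PAD4 and ICS1 the highest adjusted p with 1 array left out was 0.0439 without 8wk_LD replicate 2 and 0.0526 without 2wk_LD replicate 3. With the gene model of largest SD the ICS1 call ended (interaction -0.54, adjusted p = 0.0540). By the camera test at the preset correlation it differed for the SPL family list (median 0.10), cold acclimation list (median -0.17), cell cycle and DNA replication list (median 0.15), salicylate and jasmonate defence list (median -1.18) and vascular list (median 0.25). With an estimated correlation only the defence list was called (adjusted p = 0.00178), and the others had 0.422, 0.501, 0.414 and 0.414 in the same order. With 1 array left out the SPL family and cold acclimation calls ended, at most at 0.0788 and 0.0949, both without 2wk_LD_4wk_V replicate 1.

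The arrays of 2wk_LD_4wk_V stood apart from one another: with values centred per probe, pairs of its arrays correlated at 0.337 to 0.831, a gap of 0.493 against 0.111, 0.183 and 0.254 in 2wk_LD, 8wk_LD and 8wk_LD_4wk_V. Normalization and background may be behind it: the gap was 0.313 with Agilent processed signals (0.102 to 0.292 in the other groups) and 0.401 with the Cy5 channel alone (0.316 to 0.369), and both had to pass a bound of 0.3 to exclude this explanation, which the second did by more than the SD of the other groups' gaps and the first by less. Without background subtraction it was 0.464 (0.0634 to 0.373). Harvest on either side of lights off would need the median of 7 dark-inducible genes to span over 1 log2 unit across the 4 arrays, and it spanned 0.508 against 0.0156, 0.0453 and 0.274, short of that bound but wider than in the other groups, so it stays open too. The labels give no biological difference among the 4 pools, and none but harvest time was tested.

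The heat shock list had medians of -0.14, -0.22, 0.76 and 0.73 on replicates 1 to 4 of 8wk_LD_4wk_V. The scanner protocol, which differed for replicate 3 alone, was excluded as the whole cause by replicate 4, read with the usual protocol, whose median exceeded that of the highest 8wk_LD array by 1.02, more than the widest span within the other groups, 0.331. Signal or probe errors of single arrays could not be excluded: a second list of heat response genes, 11 of them measured, had medians of -0.074, -0.014, 0.80 and 0.16, a span of 0.873 that lies between the bounds of 0.5 and 1 set for and against it. Vernalization, which all 4 arrays share, does not set them apart, but as a cause of higher values on all 4 it stays open: the list was called up at 8 weeks (adjusted p = 0.000532, 0.0368 without replicates 3 and 4 and 0.379 with an estimated correlation).

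Photosynthesis genes were lower in 8wk_LD than in 2wk_LD, with a median log2 fold change of -0.40 over 30 genes. Apices of younger plants may carry more green leaf tissue, and a lower share of it stays open: it would also lower other genes expressed in leaves, and of 3 such lists the vascular and glucosinolate lists (medians -0.83 and -0.66) were called down at the preset correlation, whereas the trichome list (median -0.13, adjusted p = 0.0673) was not. With an estimated correlation none of the 3 was called. A difference with age within the green tissue stays open too, as untested.

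For the counts of probes and gene models, only the real split, 1 of 35, gave as many in each comparison of groups. The other splits each mix the 2 groups and 1 of 35 is the smallest possible share, so chance is not excluded. The real counts of probes and gene models were 7700 and 1716 for vernalization at 8 weeks (at most 0 and 5 otherwise). They were 22658 and 5117 at 2 weeks (at most 5 and 2). For age they were 32411 and 7216 before vernalization (at most 0 and 0) and 30986 and 7255 after it (at most 2238 and 86). For the interaction 2 of 100 splits gave as many, the real one (4138 probes and 1097 gene models) and another (7280 and 1751). The other exchanged the labels of the 2-week groups as wholes and 1 array between the 8-week groups, and so added both responses. These splits also break up the vernalization effects, so they do not test the interaction alone. Chance cannot be excluded for lists called by camera: as many arose in 2, 16, 5 and 3 of 35 splits and 27 of 100.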

How the results depend on the processing

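Leaving out pairs of arrays, scan day 2 alone, median centring of deposited values and gene models by SD were chosen after seeing the results. The number of probes past the test depended most on loess: with median centring of each array in its place, 55 probes passed for vernalization at 8 weeks (69.1% up), 977 for vernalization at 2 weeks, 5331 for age before vernalization (15.4% up against 49.8%), 3310 for age after it (14.4% up against 49.1%) and 39 for the interaction, against 7700, 22658, 32411, 30986 and 4138. Without background subtraction the counts were 15913 at 8 weeks (44.2% up against 54.8%) and 11062 for the interaction (31.6% positive against 41.9%), Agilent processed signals gave 12319 at 8 weeks, and the Cy5 channel alone gave 6873 for the interaction and 7480 at 8 weeks with 42.7% up. The deposited matrix gave 1716, 5117, 7216, 7255 and 1097 in the order above, from fewer features tested. A fit on the groups compared alone left 17933 probes and 4383 gene models for age after vernalization, but gave 41017 probes for age before it. Except for the deposited matrix, the cause was not tested.

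With each array left out in turn, probe counts ran from 4586 to 8570 for vernalization at 8 weeks, 15107 to 23367 at 2 weeks, 25008 to 34226 for age before, 24553 to 36491 for age after and 2427 to 4932 for the interaction, gene models from 1005 to 1865, 3414 to 5207, 5680 to 7610, 5767 to 7893 and 627 to 1175, and list calls from 32 to 39. Leaving out 8wk_LD replicate 2 gave the lowest counts at 8 weeks, and counts of the interaction fell by over 1.5 times without 2wk_LD replicate 2, 2wk_LD replicate 3 or 8wk_LD replicate 2. Among the arrays of scan day 2, 4527 probes and 1043 gene models passed at 8 weeks, and 1924 and 514 for the interaction. Without 8wk_LD_4wk_V replicates 3 and 4, 2842 and 644 passed at 8 weeks, and without replicates 2 and 3 the share up there was 35.8%. Without 2wk_LD_4wk_V replicates 3 and 4 the interaction had 8787 probes and 2091 gene models, and without replicates 1 and 2 1647 gene models.

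The correlation of the fold changes of vernalization at the 2 ages, 0.381 across probes, was 0.353 without background subtraction, 0.263 with processed signals, 0.294 with median centring, 0.251 with Cy5 alone, 0.289 and 0.262 without 8wk_LD_4wk_V replicates 2 and 3 or 3 and 4, and 0.296 without 2wk_LD_4wk_V replicates 3 and 4. Across gene models, 0.361, those pairs gave 0.283, 0.241 and 0.286, and with each array left out it ran from 0.321 to 0.432 across probes and 0.304 to 0.410 across gene models. With an estimated correlation, 3 of 35 list calls held. With replicate number as a block, which assumes a pairing that the numbers do not give, the counts were 7122, 20749, 31214, 29607 and 3364 probes in the same order, and 35 lists were called.

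No gene named here reversed a call in the alternatives run. Calls of named genes were the same in 501 of 515 cases with a replicate block, 497 of 515 with scan day as a block, 370 of 412 with only the groups compared, 472 of 515 in the arrays of scan day 2, 462 to 481 of 515 with pairs of vernalized arrays left out (at most 44 ended and 29 gained), 511 of 515 with median centring of the deposited values, 514 of 515 with gene models chosen by SD (the ICS1 interaction ended) and 7871 of 8240 over the omissions of 1 array, in which 51 of 249 calls ended at least once. With 1 array left out 1322 of 1360 list tests gave the same result, called or not, with 20 calls ended and 18 gained. Neither quantile scaling of intensities nor the planned median of probes was run, the latter as each feature has 1 probe. Loess, background and channel alternatives were not run for named genes or lists, which exist only in the deposited matrix. Of 238151 probes, 68672 were too dim in Cy5 to test, and changes in them would not be seen.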

Other observations

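The comparison of the age effects before and after vernalization and the check on replicate numbers were tests chosen after the results were seen. Of the gene models past the test, 1914 were higher at 8 weeks both before and after vernalization against 463 by chance, 1902 lower both times against 487, and 72 and 32 changed sides against 478 and 472. Across gene models, which are not independent replicates, the 2 age effects correlated with r = 0.705 and rho = 0.608, and across probes with r = 0.712.

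Deviations from the group mean correlated across probes at -0.250 to 0.0933 for the 24 pairs of arrays with the same replicate number in different groups, and 3 of 16 arrays correlated best with an array of their own number.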
